A study of Homo sapiens with 3 samples.

How the data were processed

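RNA sequencing had been performed on LNCaP, an established human prostate cancer cell line that responds to androgens. Per the labels' protocols, cells were cultured for 24 h and then kept for 72 h in medium with 2% fetal bovine serum, 50% of which was conditioned medium (CM). The CM was of 3 kinds, control-CM, PPAT-CM (marked as tumor in the labels) and PVAT-CM (marked as normal). PPAT stands for periprostatic adipose tissue in the series title, and the labels do not expand PVAT. RNA was extracted with RNeasy columns and libraries were made with the KAPA mRNA HyperPrep kit, per the labels' protocols. There were 3 libraries, 1 for each medium, so the design held no replicate.

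The deposited table holds whole-number counts per gene, not normalized. Per the submitters' processing notes, the tools were FastQC, Trimmomatic, HISAT2, featureCounts and edgeR with the GRCh38 genome, and their versions and settings are not given in the sources used here. The strand setting of the counting is also not given in the sources used here, so reads of overlapping and antisense genes may have been counted together, and reads from near-identical gene copies may have been split or dropped. The table has 58884 gene rows, each an Ensembl gene identifier. Symbols were found for 58472 rows in a gene name table, 58611 rows matched GENCODE release 29, whose GRCh38 coordinates are printed, and 8 rows matched neither. No row named a total or unassigned reads.

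Library totals were 16534649 counts in control-CM, 14174241 in PVAT-CM and 16965584 in PPAT-CM. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.917, 1.01 and 1.08 in the same order. Genes with a mean raw count of at least 50 over the 3 libraries were kept, 12256 in all, of which 10970 were protein-coding. The log2 ratio of scaled counts, with a pseudocount of 0.5, was used for ranking, for the 2-fold threshold and for medians. Printed fold values of single genes are ratios of TMM-scaled counts with an exact conditional binomial (Clopper-Pearson) 95% interval. Where 1 library had a count of 0, the fold was computed against a floor of 3 counts per library and is given as a lower bound, and no fold is given where both libraries were at or under that floor. Intervals and floors cover counting error only and treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

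With 1 library per medium edgeR's quasi-likelihood test has no residual degrees of freedom, so no p-value was computed, and every comparison is between libraries, not between conditions with a known spread. Gene counts past 2-fold were set beside 100 simulations of unchanged genes, with counting noise alone and with an added coefficient of variation of 10% or 20% between libraries. A total of 36 gene lists were fixed before the data were examined. For each list with at least 4 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. This leaves 32 lists assessed, of which 1.6 would lie outside that range in each comparison if genes varied independently of each other. Genes of 1 pathway can vary together between cultures, and some lists share genes, so unchanged cultures could put more lists outside it. How many was not measured. The percentile describes these libraries and is not a p-value.

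Genes were named by a rule fixed before the data were examined. It took, in each comparison, the 10 highest and 10 lowest ratios among genes with a proper symbol, the 4 members with the largest ratio in the direction of each list that stood apart, up to 2 members of each other list with the largest ratio if it reached 1.5-fold, and a few genes fixed by name, among them KLK3, BCL2, BAX, CDKN1A, MKI67 and PLIN2, whatever their values. Some of the genes this rule takes, and some of the lists, are not reported here.

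The steps were tested on simulated counts for the comparison of PPAT-CM with control-CM. Of 12264 genes in that step, 100 of 100 with a true 3-fold and 50 of 50 with a true 6-fold change passed 2-fold, 0 of 50 with a true 1.5-fold change did, and 0 of 12064 unchanged genes did. These simulations had counting noise alone. In them 4 of 50 unchanged lists of 20 genes drawn at random stood apart.

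Alternatives set before the data were examined were DESeq2 1.42.0 size factors, total counts without TMM, upper quartile factors, a mean count of at least 10 or at least 200, no filter, a pseudocount of 5, thresholds of 1.5-fold and 3-fold, a count restricted to genes whose counting interval excludes 1, and list means in place of medians. TMM factors without mitochondrial genes, protein-coding genes only, and mitochondrial genes left out were added after the data were seen. Figures were drawn with matplotlib 3.10.9.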

Results

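Gene expression was measured in 3 LNCaP libraries, from cells kept for 72 h in control-CM, in PVAT-CM or in PPAT-CM. The library totals lay between 14174241 and 16965584 counts. Genes encoded by the mitochondrial chromosome took 30.8% of the counts in control-CM, 21.1% in PVAT-CM and 15.5% in PPAT-CM. At these depths a count of 0 allowed up to 0.198 scaled CPM (counts scaled to a fixed library total) in control-CM, 0.210 in PVAT-CM and 0.163 in PPAT-CM. Each medium had 1 library, so none of the differences below has a replicate check, and intervals are 95% counting intervals.

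The first comparison asked how cells kept in medium conditioned by periprostatic adipose tissue differed from cells in control-CM, with apoptosis among the subjects named in the series title. Antigen presentation, inflammatory and interferon-related transcripts were higher in PPAT-CM, and mitochondrially encoded transcripts were lower. Of 20 antigen presentation genes 15 were measured, and all 15 were at least 1.5-fold higher, with a list median of 1.96 on the log2 scale. The count filter takes the mean over all 3 libraries, so a gene can be measured through its PPAT-CM count alone. CD74 and HLA-DRA were such genes, and they raise the tally of higher genes. HLA-B, a class I molecule (ENSG00000234745, chromosome 6, 31269491 to 31357188, GRCh38), had 756 counts in control-CM and 5298 in PPAT-CM and was 5.78-fold higher (5.36 to 6.25). The class II gene HLA-DRA was 32.0-fold higher (14.5 to 88.2), on 6 and 233 counts. The class II invariant chain CD74 had 1 and 162 counts, a ratio of 134 (23.6 to 5310). The interferon-induced GTPase gene GBP2 was 6.82-fold higher (5.20 to 9.10). Reads of HLA genes can be split among related copies, so these values are uncertain.

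Of 24 NF-kB and inflammatory targets 11 were measured. Among these 10 were at least 1.5-fold higher and 1 was lower, with a median of 1.76. RELB, a subunit of NF-kB, was 10.3-fold higher (7.07 to 15.6) and TNFAIP3, a feedback inhibitor of the pathway, was 7.14-fold higher (5.13 to 10.2). IL32 was 5.91-fold (5.17 to 6.78) and BCL3 5.07-fold higher (4.20 to 6.15). The JAK-STAT3 list, with 11 of 19 members measured, had a median of 1.14, and 8 of the 11 were at least 1.5-fold higher. SOCS3, an inhibitor of cytokine signalling (ENSG00000184557, chromosome 17, 78356778 to 78360077), was 27.4-fold higher (14.2 to 60.5), on 9 and 299 counts. JUNB was 4.59-fold (4.24 to 4.97) and OSMR 3.83-fold higher (3.11 to 4.77). Immediate early genes had a median of 0.99, with 9 of 13 at least 1.5-fold higher, among them KLF4 at 4.19-fold (3.10 to 5.75), ZFP36 at 3.34-fold (3.00 to 3.73) and EGR1 at 2.87-fold (2.49 to 3.32). Each of these lists lay above all 10000 matched random lists. They are not independent of each other, since BCL3 is in both the NF-kB and JAK-STAT3 lists and JUNB in both the JAK-STAT3 and immediate early lists.

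Pro-apoptotic genes had a median of 0.49, above all 10000 random lists, with 10 of 31 members at least 1.5-fold higher and 2 at least 1.5-fold lower. The initiator caspase gene CASP10 was 13.6-fold higher (8.58 to 22.9), on 19 and 314 counts. PMAIP1, which encodes NOXA, was 4.54-fold (3.83 to 5.40) and the death receptor adaptor FADD 3.67-fold higher (2.64 to 5.19). Anti-apoptotic genes were also higher, with a median of 0.35, below 226 of the random lists. BIRC3, which is also in the NF-kB list, was 3.42-fold (2.77 to 4.26), BAG1 1.68-fold (1.51 to 1.87), MCL1 1.56-fold (1.48 to 1.65) and BIRC2 1.5-fold higher (1.35 to 1.67). The anti-apoptotic list no longer stood apart with no filter or with a pseudocount of 5. BAX was 1.30-fold higher (1.15 to 1.47), and the interval of BCL2 included 1 (0.936 to 1.76). CDKN1A was 1.20-fold lower (1.10 to 1.31). SPATA18 was 2.27-fold (1.72 to 3.02) and GADD45A 2.20-fold lower (1.96 to 2.47).

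Type I interferon genes had a median of 0.58, with 9 of 19 at least 1.5-fold higher and 1 lower. OAS3 was 3.02-fold (2.02 to 4.61), IFITM3 2.64-fold (2.44 to 2.85), IFIT3 2.63-fold (1.80 to 3.92) and USP18 2.07-fold higher (1.56 to 2.78). With a mean count of at least 200 the median of this list was -0.036. NRF2 targets of the oxidative stress response had a median of 0.63, with 8 of 13 at least 1.5-fold higher. The ferritin gene FTH1, which has many near-identical copies, was 3.79-fold (3.68 to 3.90), GCLC 2.09-fold (1.98 to 2.20), NQO1 1.88-fold (1.71 to 2.06) and TALDO1 1.86-fold higher (1.75 to 1.97). Cytosolic ribosomal protein genes had a median of 0.24, with 9 of 35 at least 1.5-fold higher, led by RPL10A at 2.17-fold (2.11 to 2.24).

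The 13 mitochondrially encoded mRNAs were all at least 1.5-fold lower in PPAT-CM, with a median of -1.29. MT-ND3 was 3.03-fold (3.00 to 3.06), MT-ND2 2.89-fold (2.87 to 2.92), MT-CO2 2.82-fold (2.80 to 2.83) and MT-CYB 2.65-fold lower (2.63 to 2.66). Nuclear-encoded oxidative phosphorylation genes did not stand apart, with a median of 0.15. The neuroendocrine list, with 4 measured members, had a median of -0.71, with ENO2 1.94-fold (1.79 to 2.09), SYP 1.73-fold (1.15 to 2.63) and NTS 1.56-fold lower (1.53 to 1.59), and DDC 2.01-fold higher (1.95 to 2.07). It did not stand apart by its mean or without a filter. The hypoxia list, at -0.19, no longer stood apart by its mean or with a mean count of at least 10. With total counts in place of TMM it still stood apart, but its median turned to 0.050.

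KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915 to 50860764), had 10286 counts in control-CM and 4577 in PPAT-CM and was 2.72-fold lower (2.63 to 2.82). FKBP5 was 3.46-fold higher (2.90 to 4.15) and CENPN 3.22-fold higher (2.49 to 4.22).

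Most of the largest ratios were in genes with few counts in control-CM. The complement gene C4B had 1 and 1168 counts, a ratio of 963 (173 to 38086), and C4A had 3 and 399 counts, but these genes are near-identical copies whose reads can be exchanged. CPB1 had 0 and 213 counts and was at least 58.6-fold higher. CHI3L2 had 1 and 423 counts, a ratio of 349 (62.3 to 13814), and SLC5A1, a sodium-glucose transporter, 2 and 248 counts, a ratio of 102 (28.0 to 849). KRT20 was 77.3-fold (30.0 to 285), CLEC7A 38.7-fold (19.4 to 90.2) and TXNIP, an inhibitor of thioredoxin with 92 counts in control-CM and 3472 in PPAT-CM, 31.1-fold higher (25.3 to 38.7). At the other end were the kinase gene DAPK1, 28.2-fold lower (17.4 to 48.8), and the heat shock gene HSPA6, 30.3-fold lower (11.5 to 113) and similar in sequence to other HSP70 genes. COLCA1 was 24.6-fold lower (20.7 to 29.5), with overlapping genes on the other strand that the counting may not have separated. NDUFA4L2 was 8.63-fold (8.19 to 9.10), SLITRK6 8.79-fold (4.78 to 17.7), LAMA3 6.67-fold (6.12 to 7.27), CCN3 6.28-fold (3.71 to 11.3), CDH26 5.62-fold (4.92 to 6.44), FOXN4 5.61-fold (3.24 to 10.3) and CRYAB 5.6-fold lower (3.94 to 8.13).

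The remaining lists reported here did not stand apart in this comparison. Their medians were 0.10 for cholesterol synthesis, -0.21 for fatty acid synthesis and desaturation, 0.03 for fatty acid oxidation and PPAR targets, 0.37 for lipid droplets and lipolysis, 0.16 for DNA replication, -0.18 for mitosis, 0.16 for the unfolded protein response and 0.12 for the ATF4 response. They were 0.00 for glycolysis, -0.03 for histones, 0.07 for heat shock proteins, -0.01 for TGF-beta targets, 0.04 for epithelial genes, 0.11 for mesenchymal genes, 0.14 for metallothioneins, -0.25 for the glucocorticoid response and 0.11 for the insulin and IGF axis. Within these lists the secretory regulator XBP1 was 3.80-fold (3.61 to 4.0), SLC7A5 3.54-fold (2.92 to 4.32), fibronectin FN1 4.84-fold (4.59 to 5.10) and PLIN3 2.58-fold higher (2.20 to 3.03), while VIM was 3.18-fold (2.74 to 3.69), STARD4 2.64-fold (2.28 to 3.05), H1-2 2.64-fold (2.51 to 2.78) and SCD 1.90-fold lower (1.83 to 1.98). Of 33 mitosis genes 4 were measured, and the proliferation marker MKI67 had 34, 31 and 26 counts in control-CM, PVAT-CM and PPAT-CM. The lipid droplet gene PLIN2 had 15, 10 and 14 counts. Adipocyte, fibroblast, leukocyte and endothelial marker lists had at most 2 measured members each and were not assessed. The 18 leukocyte markers together had 33 counts in control-CM, 36 in PVAT-CM and 32 in PPAT-CM.

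Across all genes 482 were at least 2-fold higher and 336 at least 2-fold lower in PPAT-CM. Simulated unchanged libraries gave 0.14 and 0.09 with counting noise alone, 2.06 and 1.59 with a 10% coefficient of variation between libraries, and 135 and 129 with 20%. With total counts in place of TMM the numbers were 905 higher and 177 lower. Of the 482 higher genes 444 were protein-coding, and of the 336 lower genes 202, against 10970 of all 12256 genes kept. The median log2 ratio was 0.05 over protein-coding genes, -0.29 over long intergenic noncoding RNA genes and -0.28 over antisense genes. The lower genes thus held a larger noncoding share, and its cause was not tested. The true spread between cultures was not measured.

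**Figure D1:**
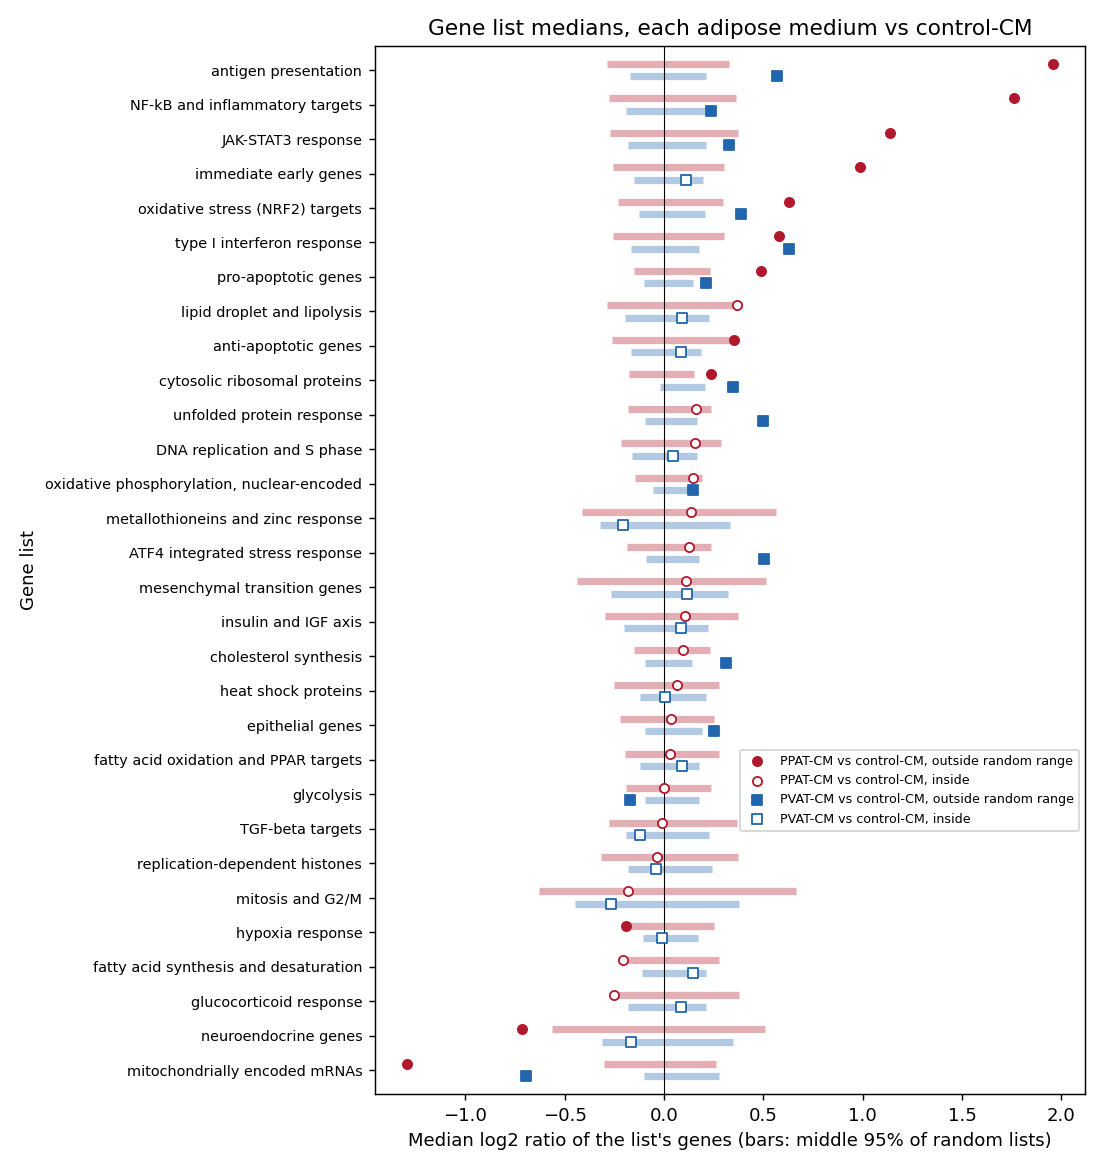
Median log2 ratio of assessed gene lists (horizontal axis) in PPAT-CM (red circles) and PVAT-CM (blue squares) against control-CM, with bars for the middle 95% of matched random lists and filled symbols for lists outside that range. Antigen presentation lies at 1.96 in PPAT-CM and 0.57 in PVAT-CM, and mitochondrially encoded mRNAs at -1.29 and -0.70.

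The second comparison set PVAT-CM against control-CM. Over all genes the differences were smaller, and stress response and interferon genes were higher while mitochondrially encoded mRNAs were lower. The ATF4 and unfolded protein response medians given below were larger than those of PPAT-CM against control-CM, at 0.12 and 0.16. The type I interferon median was close to that of PPAT-CM against control-CM, at 0.58. Between the 2 adipose media the interferon list did not stand apart, with a median of 0.11 for PPAT-CM against PVAT-CM. Type I interferon genes had a median of 0.63, with 10 of 19 at least 1.5-fold higher and 1 lower. IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) was 3.14-fold (2.76 to 3.59), OAS3 2.79-fold (1.84 to 4.34), IFIT3 2.79-fold (1.89 to 4.19) and OAS1 2.24-fold higher (1.5 to 3.41). Antigen presentation genes had a median of 0.57, with 7 of 15 at least 1.5-fold higher, among them HLA-B at 1.95-fold (1.78 to 2.13), TAP1 at 1.94-fold (1.34 to 2.85) and B2M at 1.68-fold (1.62 to 1.75). The 1 gene past 1.5-fold on the lower side was CD74. Its counts in both libraries were at or under the floor, so it cannot be called lower. The ATF4 list of the integrated stress response had a median of 0.50, with 10 of 21 at least 1.5-fold higher, and the unfolded protein response list also 0.50, with 5 of 19. The cystine transporter gene SLC7A11 was 2.20-fold (2.01 to 2.40), ATF3 1.95-fold (1.71 to 2.21), GDF15 1.79-fold (1.75 to 1.84), TRIB3 1.76-fold (1.63 to 1.90), PDIA6 1.85-fold (1.58 to 2.15) and HYOU1 1.74-fold higher (1.58 to 1.92).

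Other lists stood apart by smaller medians. NRF2 targets were at 0.39, with GCLM 1.64-fold higher (1.44 to 1.87). Ribosomal protein genes were at 0.35, JAK-STAT3 genes at 0.33, with OSMR 1.86-fold higher (1.46 to 2.38), and cholesterol synthesis genes at 0.31. Epithelial genes were at 0.25 and NF-kB targets at 0.24, with TNFAIP3 1.92-fold higher (1.28 to 2.89). Pro-apoptotic genes were at 0.21, with HRK 2.22-fold (1.65 to 3.02), BBC3 1.58-fold (1.38 to 1.81) and FAS 1.57-fold higher (1.18 to 2.08). Nuclear-encoded oxidative phosphorylation genes were at 0.15, with none of 32 members reaching 1.5-fold. With a mean count of at least 200 the NF-kB and pro-apoptotic lists no longer stood apart, and the epithelial list did not by its mean. On the lower side, mitochondrially encoded mRNAs were at -0.70, with MT-CYB 1.73-fold lower (1.72 to 1.74), and glycolysis genes at -0.17, with LDHA 1.43-fold lower (1.39 to 1.48).

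Medians of lists that did not stand apart were 0.15 for fatty acid synthesis, 0.09 for fatty acid oxidation, 0.09 for lipid droplets, 0.08 for anti-apoptotic genes, 0.05 for DNA replication, -0.27 for mitosis, -0.01 for hypoxia, -0.04 for histones and 0.01 for heat shock proteins. Those of immediate early genes, TGF-beta targets, mesenchymal genes, neuroendocrine genes, metallothioneins, the glucocorticoid response and the insulin and IGF axis were 0.11, -0.12, 0.12, -0.16, -0.21, 0.09 and 0.08. By its mean, 0.25, the immediate early list did stand apart, at percentile 99.5. KLK3 was 1.03-fold (1.00 to 1.06), BAX 1.20-fold (1.05 to 1.37) and CDKN1A 1.23-fold higher (1.13 to 1.34), and the interval of BCL2 included 1 (0.763 to 1.53).

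Among single genes the adrenoceptor gene ADRA2A had 332 and 1282 counts and was 4.11-fold higher (3.64 to 4.65), APOL6 3.74-fold (2.46 to 5.86), CLEC7A 3.32-fold (1.45 to 8.53) and APOL3 3.29-fold (1.63 to 7.19). C4B had 1 and 37 counts, C4A 3 and 21 and SLC5A1 2 and 14. CPB1, with 0 and 1 counts, and CD74, with 1 and 0, were at or under the floor and have no fold here. The interval of CHI3L2, on 1 and 4 counts, included 1 (0.421 to 210). DAPK1 was 6.88-fold (5.16 to 9.32), CRYAB 4.34-fold (3.05 to 6.30), COL5A2 3.17-fold (2.81 to 3.58), AOC1 2.96-fold (2.27 to 3.91), IL1RN 2.88-fold (1.88 to 4.55) and BASP1 2.82-fold lower (2.10 to 3.83). In all, 57 genes were at least 2-fold higher and 54 at least 2-fold lower. Unchanged libraries with a 10% coefficient of variation gave 2.73 and 2.86, and with 20% they gave 136 and 140. The observed standard deviation of the log2 ratios, 0.324, lay between the 10% setting (0.246) and the 20% setting (0.435). Unchanged libraries with a variation between these settings could thus give the observed spread.

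The third comparison set PPAT-CM against PVAT-CM. NF-kB targets had a median of 1.64, with 9 of 11 at least 1.5-fold higher in PPAT-CM, antigen presentation genes 1.40 (14 of 15), JAK-STAT3 genes 0.94 (8 of 11), immediate early genes 0.61 (7 of 13) and pro-apoptotic genes 0.24 (8 of 31, with 2 lower). CD74 was at least 41.9-fold higher, on 0 and 162 counts. HLA-DRA was 22.6-fold (11.3 to 52.9), SOCS3 17.8-fold (10.3 to 33.9), CASP10 17.4-fold (10.2 to 32.2), GBP2 9.70-fold (7.0 to 13.8), RELB 7.04-fold (5.07 to 10.0) and PMAIP1 2.87-fold higher (2.49 to 3.33). TXNIP was 45.6-fold (35.3 to 60.1), KRT20 29.1-fold (15.6 to 61.1) and the protease gene MMP7 18.7-fold higher (8.40 to 51.9).

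Lists lower in PPAT-CM than in PVAT-CM included mitochondrially encoded mRNAs at -0.55, neuroendocrine genes at -0.47, ATF4 genes at -0.46, unfolded protein response genes at -0.30 and cholesterol synthesis genes at -0.15. The neuroendocrine list, of 4 members, no longer stood apart in 2 of 10 alternatives, by its mean and with no filter. GDF15 was 2.29-fold (2.24 to 2.35), GADD45A 2.76-fold (2.47 to 3.09), BBC3 2.14-fold (1.86 to 2.46), DDIT3 1.93-fold (1.80 to 2.08), SEL1L 1.76-fold (1.63 to 1.89) and SC5D 2.18-fold lower (2.05 to 2.32). KLK3 was 2.81-fold lower (2.72 to 2.91). COLCA1 was 19.2-fold (16.1 to 23.0), HSPA6 19.7-fold (7.30 to 74.5), FOXN4 8.14-fold (4.78 to 14.8), SI 6.91-fold (4.95 to 9.85) and ATP1B1, a sodium pump subunit, 4.69-fold lower (4.45 to 4.94). The type I interferon list did not stand apart, with a median of 0.11, though IFI6 was 3.22-fold (2.85 to 3.65) and IFIT1 3.01-fold lower (2.39 to 3.83). The other lists reported here that did not stand apart had medians from -0.16 for fatty acid synthesis to 0.25 for anti-apoptotic genes. By their means NRF2 targets, at 0.30, and anti-apoptotic genes, at 0.36, did stand apart, at percentiles 99.4 and 98.4. In all, 300 genes were at least 2-fold higher and 180 at least 2-fold lower, against 2.09 and 1.75 with a 10% coefficient of variation and 139 and 131 with 20%.

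**Figure D2:**
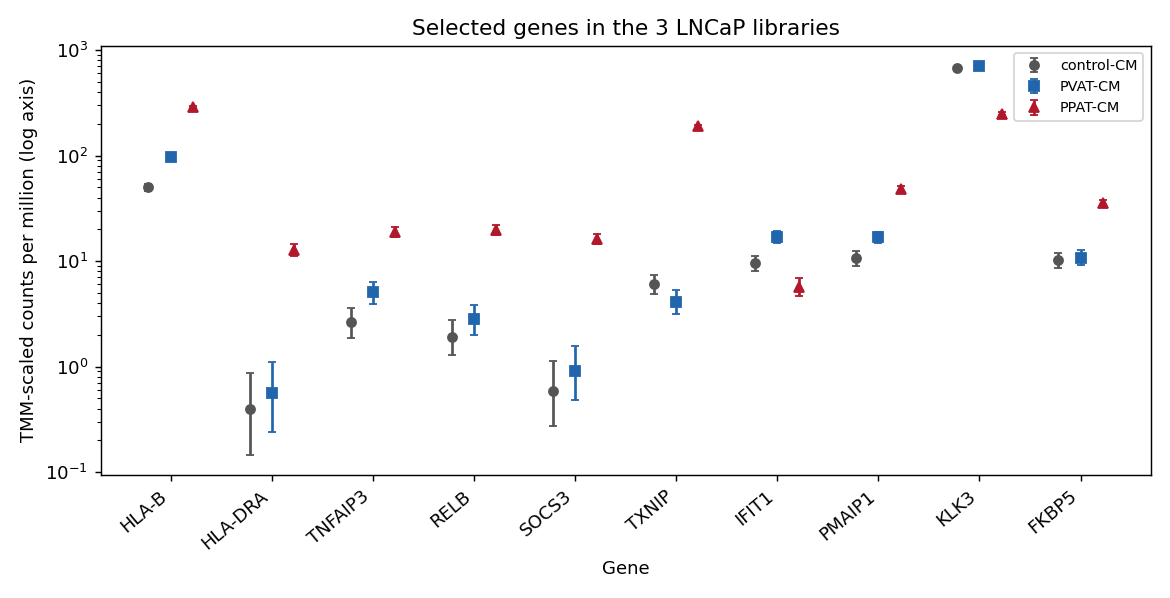
TMM-scaled CPM (log axis) of 10 genes in the control-CM (grey), PVAT-CM (blue) and PPAT-CM (red) libraries, with exact 95% Poisson intervals that cover counting error only. HLA-DRA, RELB, SOCS3 and TXNIP lie higher in PPAT-CM than in the other libraries, KLK3 lies lower, and IFIT1 is highest in PVAT-CM.

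The libraries were also compared as wholes. Beyond counting error, the standard deviation of log2 ratios over genes was 0.58 between PPAT-CM and control-CM, 0.29 between PVAT-CM and control-CM and 0.47 between PPAT-CM and PVAT-CM, so the first was 1.98 times the second, or 1.19 times with no filter on low counts. Of the 482 genes at least 2-fold higher in PPAT-CM than in control-CM, 421 were also above control-CM in PVAT-CM (87.3%), and the median PVAT-CM ratio of all 482 was 1.34-fold. Of the 336 lower genes, 303 were below it (90.2%). The shared control gives such shares without any change. Pooled over simulated unchanged libraries, 204 of 206 higher and 152 of 159 lower genes went the same way with a 10% coefficient of variation, and 95.6% and 89.7% with 20%. In total 42 genes were at least 2-fold higher and 29 at least 2-fold lower in both adipose media, against 2.24 and 1.48 for independent lists, which leave out the shared control. Simulated unchanged libraries sharing a control gave 0.4 and 0.08 with a 10% coefficient of variation and 28.9 and 11.5 with 20%. Across genes, which are not independent replicates, Pearson's r between the ratios was 0.570 and Spearman's rho 0.557. The shared control library alone gave 0.515 and 0.475 in simulations of unchanged libraries with counting noise. The covariance was 0.110, against 0.00892 simulated with counting noise, 0.0299 with a 10% coefficient of variation and 0.0941 with 20%. With 1 control library it could not be split, and part of the excess may come from the shared control.

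**Figure D3:**
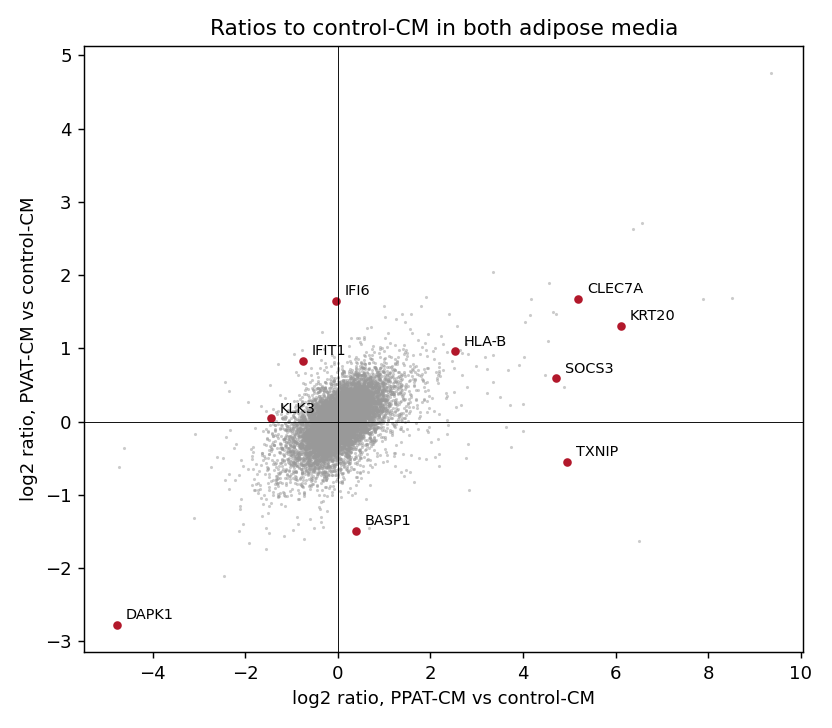
Log2 ratio to control-CM of each of 12256 genes in PPAT-CM (horizontal axis) and PVAT-CM (vertical axis), with selected genes in red. Pearson's r across genes is 0.570, and DAPK1 lies low in both media while TXNIP and KLK3 depart from control-CM mainly in PPAT-CM.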

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

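The genes below were taken because, among genes named by the rule fixed before the data were examined, their ratios to control-CM went in opposite directions in PPAT-CM and PVAT-CM with both counting intervals excluding 1. The difference was not tested, since each medium had 1 library, and for highly expressed genes a very small ratio is enough to meet this condition. All values are log2 ratios to control-CM, in PPAT-CM first and in PVAT-CM second.

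Higher in PPAT-CM and lower in PVAT-CM were TXNIP at 4.95 and -0.55, GCLC at 1.06 and -0.46, BASP1 at 0.40 and -1.49, and the metallothionein gene MT2A at 0.58 and -0.21.

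Lower in PPAT-CM and higher in PVAT-CM were several stress and apoptosis genes. These were BBC3 at -0.44 and 0.66, GDF15 at -0.35 and 0.84, GADD45A at -1.14 and 0.33, DDIT3 at -0.62 and 0.33, CDKN1A at -0.26 and 0.30, PSAT1 at -0.45 and 0.45, SEL1L at -0.36 and 0.45, and DNAJB11 at -0.38 and 0.27. STC2 was at -0.14 and 0.62, but with total counts without TMM its PPAT-CM value turned to 0.098. The interferon-induced gene IFIT1 was at -0.75 and 0.83. Sterol and lipid genes in this group were SQLE at -0.46 and 0.34, MSMO1 at -0.46 and 0.31, SC5D at -0.82 and 0.31, and SCD at -0.93 and 0.14. APOD, a lipocalin gene, was at -1.94 and 0.26, and CFD, which encodes complement factor D, at -0.54 and 0.44. The epithelial genes ESRP1 and DSP were at -0.26 and 0.32 and at -0.36 and 0.32. FOXN4 was at -2.45 and 0.54, and SI at -2.35 and 0.42. KLK3 was at -1.45 and 0.046, so its PVAT-CM ratio was close to 0. The same holds for COX6A1 at -0.63 and 0.12 and RPL18 at -0.55 and 0.095.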

How the results depend on the processing

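No paired analysis was possible because each medium had 1 library, and for the same reason no library could be left out. Alternatives that leave out or rescale by mitochondrial genes, or keep protein-coding genes only, were chosen after seeing the data. The order of the counts below is PPAT-CM against control-CM higher and lower, PVAT-CM against control-CM higher and lower, then PPAT-CM against PVAT-CM higher and lower, with main values 482, 336, 57, 54, 300 and 180. At 1.5-fold they were 1475, 1068, 386, 428, 1049 and 744, and at 3-fold 153, 63, 11, 6, 97 and 27, by construction of the threshold. With a mean count of at least 10 they were 936, 877, 301, 475, 780 and 587, with at least 200 they were 248, 144, 13, 11, 131 and 78, and with no filter 5023, 4541, 3880, 4475, 5076 and 3981, where more or fewer low-count genes entered. With total counts without TMM the first 4 were 905, 177, 100 and 31, with the median of all genes moved by 0.24 in PPAT-CM and 0.13 in PVAT-CM against control-CM and by 0.11 between the adipose media, and the share of higher among called genes went from 58.9% to 83.6%, from 51.4% to 76.3% and from 62.5% to 76.9%. Every other alternative left these counts within 1.5 times.

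The ratio of the PPAT-CM to the PVAT-CM distance from control-CM, 1.98, was 1.75 with a mean count of at least 10 and 1.19 with no filter, and Pearson's r across genes was 0.509 and 0.505. The cause was not tested. The number of lists standing apart stayed within 11 to 13, 13 to 17 and 10 to 15 in the 3 comparisons. The hypoxia response median in PPAT-CM against control-CM turned to 0.050 with total counts without TMM, by the shift of all genes, and the type I interferon response median turned to -0.036 with a mean count of at least 200; that cause was not tested. Over all alternatives, with the list mean among them, the antigen presentation value in that comparison ranged from 1.87 to 2.34, the highest being the mean. That of NF-kB targets ranged from 1.45 to 2.00. Of 2873 recomputed values of 303 single-gene ratios, 2689 stayed within the counting interval, 184 moved outside it and 0 of those at least 2-fold changed sign. With each of the 182 genes taken in all 3 comparisons, 33 of 5226 recomputed values had the other sign, all of small ratios. Of these ratios 4 had a counting interval excluding 1, the largest -0.14.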

Other observations

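Tests of mitochondrial scaling, of respiratory chain mRNA, of leukocyte markers, of reads assigned to the wrong library, of the lower genes under control noise, of MondoA targets and of complement lists with added members were chosen only after their result, or part of it, was seen. The gene families of the next paragraph were written down after genes with large ratios had prompted them. This was done before the family's other members were examined, apart from those that are also in the hypoxia list. Those are KLF10 and BHLHE40 of the MondoA targets, and P4HA1 and P4HA2 of the collagen-modifying enzymes.

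In PPAT-CM against control-CM 4 gene families were examined that genes with large ratios had prompted, leaving out those genes. A list of 7 other measured complement genes had a median of 0.54, beyond all but 72 of 10000 matched random lists, with C1S at 2.01 on the log2 scale and CD55 at -0.55. This list left out CFD, at -0.54, and CLU, at -2.19. With CFD the median of 8 genes was 0.23, and 1239 random lists were higher. With both it was -0.073 over 9 genes, of which 4 were higher and 5 lower, so whether complement genes other than C4A and C4B were higher as a group stays undecided. Collagens and collagen-modifying enzymes, 17 measured, had a median of -0.24, and 228 random lists were lower, with COL12A1 at -1.04 and COL6A2 at -0.71, but P4HB at 0.68. The median member was P4HA1, at -0.24, which is also in the hypoxia list, so this family was not wholly unexamined beforehand. Of retinoic acid targets other than PLAAT4, 3 were measured, fewer than the 4 required, so their median of 1.04 decides nothing. MondoA and ChREBP targets other than TXNIP had a median of 0.15 over 10 genes, of which 4 were at least 1.5-fold higher, among them ARRDC4 at 1.54, and 1 was at least 1.5-fold lower, so that median does not decide either, although it misses the percentile set for it.

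Antigen presentation and NF-kB genes were higher in the PPAT-CM library. Leukocytes or their RNA carried in with the medium are argued against for the list as a whole, since the upper limit of the leukocyte marker excess, with counting error in both libraries, was 0.0553% of the antigen presentation excess, with PTPRC, TYROBP and CD68 at 0 counts, LAPTM5 at 3 and LYZ at 5. This holds under an assumed limit of 1%, set after the counts were seen. The share that leukocyte RNA would give was not measured. For the class II transcripts alone, with 425 excess counts, leukocyte RNA as a source cannot be told apart from expression by LNCaP, because no measured leukocyte profile was used. GC content or gene length bias is argued against by an antigen presentation median of 2.00 after adjustment for both. A difference between single cultures unrelated to the medium cannot be told apart from an effect of the medium with 1 library per medium, and a response to PPAT-CM stays open and untested.

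Mitochondrially encoded RNA was lower in both adipose-medium libraries. Besides the mRNAs, the mitochondrial rRNA genes had medians of -1.20 in PPAT-CM and -0.62 in PVAT-CM against control-CM. Those of the mitochondrial tRNA genes were -1.29 and -0.79. Scaling distorted by a few abundant mitochondrial genes is argued against, since with factors from nuclear genes the higher of the 2 medians was still -0.70. Less mRNA for the whole respiratory chain is argued against by the nuclear-encoded genes, whose lower median in the 2 comparisons was 0.15. A difference between single cultures, or between their RNA and libraries, that is unrelated to the medium cannot be told apart from an effect of the medium with 1 library per medium.

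The PVAT-CM library differed from control-CM in the same direction as the PPAT-CM library. Noise in the shared control and a shared difference cannot be told apart. The 300 genes at least 2-fold higher in PPAT-CM than in PVAT-CM, chosen without the control, had a median PVAT-CM ratio to control-CM of 0.11 (95% bootstrap interval over genes 0.05 to 0.18), and the lower genes -0.035 (-0.10 to 0.05). An interval above 0 had been set to count against control noise, but genes of 1 control library are not independent, so it leaves out a coordinated difference in that culture. Whether reads of the PPAT-CM library were assigned to the PVAT-CM library was not decided. Over 85 genes the median PVAT-CM excess was 4.78% (3.81 to 7.25) of the PPAT-CM count. CD74, with 0 counts in PVAT-CM, allows at most 2.30% for such reads, and 56 of the 85 genes lay above that. However, the 85 genes were chosen by their ratio to the same control library, so noise in that library can raise the excess by itself. A shared response to adipose media stays open and untested.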
